A study of Mus musculus with 2 samples.

How the data were processed

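Long-read RNA sequencing was performed on C2C12 myotubes, the multinucleated muscle cells that the mouse C2C12 myoblast line forms on differentiation in culture. There were 2 libraries in 1 group, and per the labels these were biological replicates 1 and 2, each with its own biosample entry from the same cell line. The labels do not say how many days the cells had differentiated or whether the cultures were differentiated separately, so differences between the libraries measure only the spread between these samples, which may be technical. No p-value here includes a measured spread between samples. Fisher's and binomial tests cover the counting error of reads, and permutation tests the spread across genes.

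The deposited counts are whole reads assigned to each transcript model in each library, with no normalization, per the file headers. The models carry the source name TALON, a program that assigns long reads to annotated or unannotated transcript models, and per the deposited file listings they refer to the mm10 assembly and the GENCODE M21 annotation. The aligner, the TALON version and its filters are not given in the sources used here. Each model has a deposited class. Known models have the introns of an annotated transcript. Incomplete splice matches have a consecutive part of such introns. The unannotated-chain classes have an intron chain that is not annotated, through a new combination of annotated introns, an unannotated intron or an unannotated splice site. Genomic, antisense and intergenic models make up the rest. The classes were used as deposited. The exon coordinates of the deposited models were read from the deposited transcript annotation of each library, and all 25968 of the 25968 known endogenous models had the same exons in the M21 reference.

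Gene counts were the sum of reads over all models of a gene. CPM values, the counts per 1e6 endogenous reads, were computed here from those counts, leaving out the spike-in RNAs. No length correction was made, because a long read was taken to stand for a single molecule, which was not tested. The libraries held 2044692 and 2131138 endogenous reads. A single read was worth 0.489 CPM in replicate 1 and 0.469 CPM in replicate 2, and the limit that a count of 0 allows, taken as 3 reads, was 1.47 and 1.41 CPM. Models were matched between libraries by identifier when known and otherwise by gene and intron chain. Single-exon models of a gene were pooled. Values are means ± SD over both libraries unless stated otherwise. Intervals of shares of reads are 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only.

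Before the data were examined, 16 gene lists to be set against a cell cycle list, 30 paralog pairs, the tests and the rule for named genes were fixed. Lists were compared on median log2(CPM + 1), with a pseudocount of 1 CPM and two-sided permutation tests across genes (100000 resamples) adjusted by Benjamini-Hochberg over the lists. Genes are not independent replicates. Paralog pairs and the first against the second transcript of a gene were tested with two-sided exact binomial tests in each library and called where both libraries passed an adjusted p of 0.05 in the same direction. The libraries were compared with two-sided Fisher's exact tests per gene, for genes with at least 10 reads over both libraries, and a gene was called at an adjusted p under 0.05 and at least 2-fold. Transcript usage was tested the same way against the other reads of the gene, for genes with at least 20 reads in each library and without a fold minimum. Both tests compare those libraries, not conditions. Each list's median log2 ratio between libraries was placed among 10000 random lists matched on expression. That median was taken over members with at least 10 reads over both libraries, and each random list had as many genes. A major isoform was a known or unannotated-chain transcript with at least 10% of the gene's reads in both libraries, and unannotated-chain transcripts were counted from 5 reads in each library.

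Named genes were, per list, the 4 members with the highest mean CPM, members with no read (up to 3 by alphabetical order) and members called between libraries. In addition, all paralog pairs, the 10 most-read genes of the splicing list with enough reads, called splicing genes whose first transcript was unannotated, the 10 most-read genes of all, the 5 called genes with the largest fold in each direction among those with at least 20 reads, the 8 most-read unannotated-chain transcripts and the 2 most-read antisense and intergenic loci were named. The other called genes with 0 reads in a library were added after their values were seen.

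The gene test was run on simulated counts for the real genes, drawn with counting error only. In these, 200 genes with at least 50 reads over both libraries were changed. The gene test recovered 88 of 100 genes changed 2.5-fold and 100 of 100 changed 4-fold, and it called 6 of 11621 unchanged genes. The usage test, on counts drawn the same way, recovered 191 of 200 switched transcripts and called 2 of 168586 others. Switched genes had at least 100 reads in each library. Recovery at fewer reads was not simulated. The real libraries differed by more than counting error, so the calls among unchanged genes and transcripts do not measure false calls in the real libraries. In 200 comparisons of randomly drawn lists the permutation test gave 13 p-values under 0.05.

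The alternatives were other scalings (edgeR TMM and DESeq2 size factors), read minimums, pseudocounts, sets of transcript classes, an edgeR exact test with an assumed dispersion of 0.1, and leaving out each replicate. The planned comparison of unannotated-chain reads between endogenous RNA and the SIRV spike-ins, synthetic RNAs with known splice forms, was not used, since the deposited annotation holds 1 single-exon model per SIRV gene so that spliced SIRV reads fall in the unannotated classes, and the ERCC spike-ins are single-exon. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and blastn 2.17.0 for alignments between pseudogenes and M21 transcripts.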

Results

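Long RNA sequencing reads were counted in C2C12 myotubes from 2 biological replicates. Replicate 1 had 2046576 reads over 212319 transcript models and replicate 2 had 2133422 reads over 216198 models. Reads of annotated genes made up 92.4% and 93.1% of endogenous reads, and 16242 and 16120 annotated genes were detected. Models with a single read made up 58.7% and 58.5% of all models. Mitochondrial genes held 1970 and 2060 reads. The series gives a single group, so genes and transcripts were compared within the libraries, and the libraries were compared with each other.

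The most-read gene was the skeletal muscle actin Acta1 (ENSMUSG00000031972.5, chromosome 8, 123891769 to 123894751), at 8549.6 ± 285 CPM. The sarcoplasmic reticulum calcium pump Atp2a1 (ENSMUSG00000030730.12, chromosome 7, 126445858 to 126463108) followed at 7645 ± 71.8 CPM, then the slow troponin C gene Tnnc1 at 4461 ± 7.67 CPM. Among the 10 most-read genes were also the myogenic transcription factor Myog at 3312 ± 140.4 CPM, the glycolytic genes Ldha, Pkm, Aldoa and Eno3 between 2840.3 and 3147 CPM, and the collagen gene Col3a1 at 2825 ± 225 CPM. The processed pseudogene Gm15459 was in 4th place by reads at 3705 ± 18.9 CPM. It aligned to the chaperone gene Hspa8 at 99.7% identity, and Hspa8 itself had 192 and 158 reads.

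Which gene programmes the myotubes expressed was addressed with gene lists set against a cell cycle list. Sarcomere genes, which encode the contractile apparatus, had a median of 306 CPM, and 42 of 43 members were detected in both libraries. Beside Acta1 and Tnnc1 the list was led by the fast troponin C gene Tnnc2 (2712 ± 11.0 CPM) and the embryonic myosin heavy chain gene Myh3 (2700.1 ± 309.7 CPM), while the slow and ventricular light chain gene Myl3 had 0 reads. The median of the cell cycle list was 24.4 CPM, with the ribonucleotide reductase genes Rrm2 (354 ± 28.6 CPM) and Rrm1 (50.3 ± 3.51 CPM) and the replication licensing genes Mcm2 (76.2 ± 5.62 CPM) and Mcm7 (50.2 ± 7.23 CPM) as its highest members. The sarcomere median lay 3.60 log2 units above the cell cycle median (3.68 and 3.45 in the libraries taken singly; permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-05). With reads of known transcripts only, the difference was 1.86 (permutation p = 0.00245).

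The other muscle lists also exceeded the cell cycle list. Myogenic regulators had a median of 77.8 CPM and a difference of 1.63 (adjusted permutation p = 0.000542), led by Myog, the cell cycle inhibitors Cdkn1c (1565 ± 11.1 CPM) and Cdkn1a (1422 ± 67.1 CPM) and the transcription factor Mef2a (327 ± 14.1 CPM). Pax3, a regulator of muscle precursors, had 0 reads. Myoblast fusion genes had a median of 87.4 CPM and a difference of 1.77 (adjusted permutation p = 7.27e-05), led by the fusion protein gene Mymk (1160.1 ± 24.96 CPM), the integrin genes Itgb1 (718 ± 13.6 CPM) and Itga7 (626 ± 7.82 CPM) and the M-cadherin gene Cdh15 (377 ± 17.5 CPM). Genes of excitation-contraction coupling, which links the action potential to calcium release, had a median of 107 CPM and a difference of 2.08 (adjusted permutation p = 4.8e-05). After Atp2a1 the leading members were its paralog Atp2a2 (1517 ± 10.8 CPM), the sarcoplasmic reticulum protein gene Srl (1223 ± 0.231 CPM) and the calsequestrin gene Casq2 (343 ± 6.21 CPM), and the pump regulators Pln and Sln had 0 reads. Neuromuscular synapse genes had a median of 124 CPM and a difference of 2.30 (adjusted permutation p = 0.000533), led by the acetylcholine receptor subunit genes Chrna1 (1719 ± 82.4 CPM), Chrnd (550.5 ± 38.4 CPM) and Chrng (464 ± 21.6 CPM) and the kinase regulator Prkar1a (934 ± 41.1 CPM). Genes with muscle splice forms had a median of 168 CPM and a difference of 2.73 (adjusted permutation p = 2e-05).

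Energy metabolism and housekeeping genes stood highest. Glycolysis genes had a median of 426 CPM and a difference of 4.07, led by Ldha (3147 ± 211 CPM), Pkm (3112 ± 45.7 CPM), Aldoa (3008 ± 241 CPM) and Eno3 (2840.3 ± 188 CPM). Oxidative phosphorylation genes had a median of 378 CPM and a difference of 3.90, led by the ATP synthase genes Atp5b (2514 ± 38.04 CPM) and Atp5a1 (1603 ± 80.4 CPM), Sdha (675 ± 17.5 CPM) and Uqcrc1 (627 ± 61.9 CPM). The housekeeping list had a median of 392 CPM and a difference of 3.95, led by the ribosomal protein gene Rplp0 (2255 ± 159 CPM), the elongation factor genes Eef2 (1951 ± 80.4 CPM) and Eef1a1 (1494 ± 144 CPM) and the cytoplasmic actin gene Actg1 (701 ± 65.8 CPM). The adjusted permutation p was 2e-05 for each of these 3 lists. Gapdh, a member of the glycolysis list, had 62 and 51 reads, and its pseudogene Gm13394 had 1504 and 2322.

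Among markers of other cells, matrix genes stood above the cell cycle list. The fibroblast and matrix list had a median of 70.7 CPM, 1.50 log2 units above the cell cycle list (adjusted permutation p = 0.00112), with Col3a1, the smooth muscle actin gene Acta2 (1123 ± 90.7 CPM), Sparc (896 ± 33.4 CPM) and Col5a1 (348 ± 29.4 CPM) highest and Dcn, Lum and Tcf21 at 0 reads. Genes of reserve and undifferentiated myoblasts had a median of 23.2 CPM. The list did not differ detectably from the cell cycle list (difference −0.07, permutation p = 1), with Itga7, Megf10 (158 ± 0.460 CPM), Spry1 (72.9 ± 9.04 CPM) and Fgfr4 (46.6 ± 5.75 CPM) highest and Calcr and Chrdl2 at 0 reads. The bone and cartilage list had a median of 0.479 CPM and lay below the cell cycle list (difference −4.10, adjusted permutation p = 3.56e-05), although the matrix phosphoprotein gene Spp1 reached 710 ± 36.5 CPM, followed by Sox9 (45.9 ± 4.07 CPM), Dmp1 (20.5 ± 3.46 CPM) and Runx2 (16.5 ± 3.92 CPM). Acan, Col10a1 and Ibsp had 0 reads.

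The adipocyte, neuron and glia, and endothelial and immune lists each had a median of 0 CPM (difference −4.67, adjusted permutation p = 2e-05 for each). In the adipocyte list 6 of 10 genes had no read, among them Adipoq, Cfd and Cidec, and the highest members were Cebpa (11.5 ± 2.37 CPM) and Pparg (8.39 ± 0.584 CPM). Retn and Lpl had 1 read over both libraries each. In the neuron and glia list 9 of 15 genes had no read, among them Gap43 and Gfap. Stmn2 (14.4 ± 1.78 CPM) and Tubb3 (14.1 ± 3.99 CPM) were its highest members, and Nefm had 3 and 1 reads and Map2 had 2 and 1. In the endothelial and immune list 9 of 14 genes had no read, among them Adgre1 and Cd3e, and Vwf had 9 and 5 reads, Itgam 0 and 4, Cd68 1 and 1, and Csf1r 1 and 0. The list of non-coding RNAs and imprinted genes did not differ detectably from the cell cycle list (difference −0.47, permutation p = 0.316, adjusted p = 0.337). Its leading member was H19 (1687 ± 7.15 CPM), followed by Malat1 (923 ± 76.1 CPM), Neat1 (152 ± 29.8 CPM) and Gas5 (57.1 ± 9.80 CPM), while the imprinted genes Dlk1, Meg3 and Mirg had 0 reads.

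**Figure D1:**
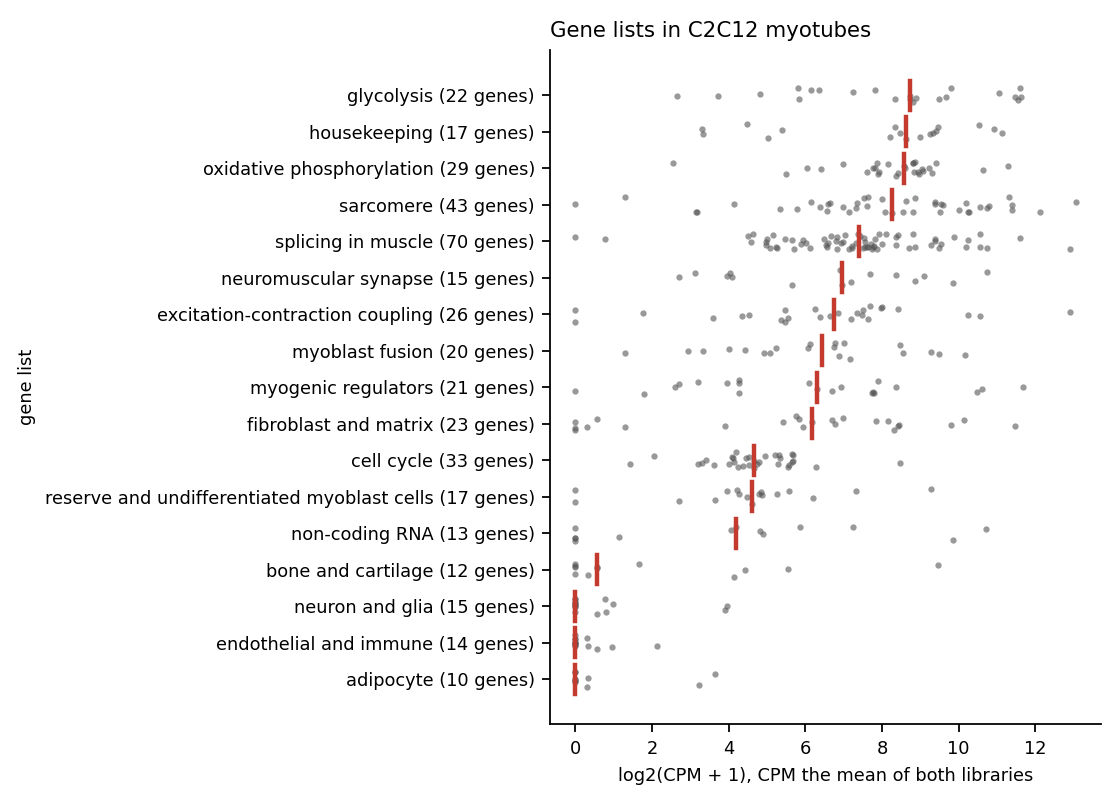
Each point is a gene of a list, at log2(CPM + 1) with CPM the mean of both libraries, and the red line is the list median. The glycolysis, housekeeping, oxidative phosphorylation and sarcomere medians lie highest, at 306 to 426 CPM, and 3 lists of other cell types have a median of 0 CPM.

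Sarcomeric myosin heavy chain genes mark the stage of muscle fibres. Myh3, the embryonic gene (ENSMUSG00000020908.14, chromosome 11, 67078300 to 67102291), held 67.9% ± 2.23 of the reads of 6 such genes (SD, n = 2). The fast gene Myh1 held 18.9% ± 0.309, the fast gene Myh4 6.50% ± 1.64, the slow gene Myh7 3.50% ± 0.0970 and the perinatal gene Myh8 3.15% ± 0.368, and Myh2 had 3 reads in each library. Myh3 and Myh8 together held 69.8% (exact 95% interval 68.7 to 70.8) of 7644 reads in replicate 1 and 72.4% (71.5 to 73.3) of 8949 reads in replicate 2, or 71.1% ± 1.86. The intervals of the libraries did not overlap, so they differed by more than counting error.

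**Figure D2:**
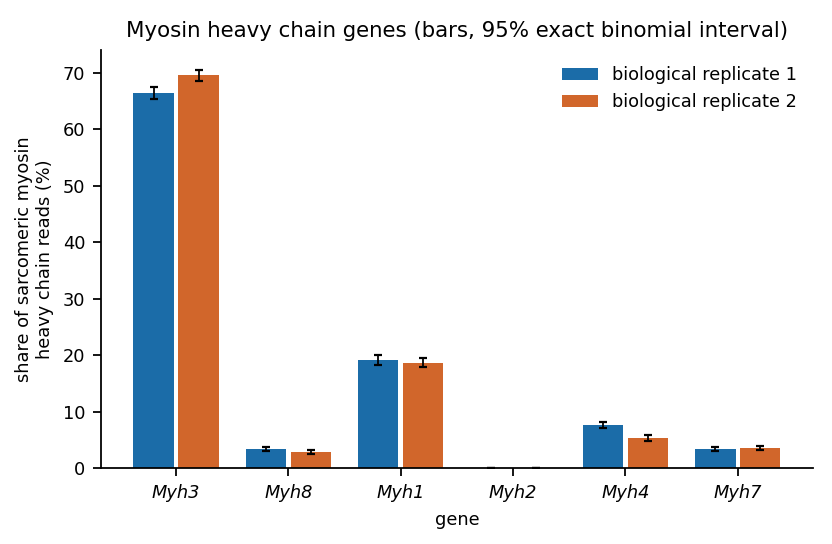
Bars give each gene's percent of the reads of the 6 sarcomeric myosin heavy chain genes in each library, with 95% exact binomial intervals. Myh3 holds 66.4% and 69.5% of the reads, above Myh1 at 19.1% and 18.7%.

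Paralog pairs were compared with a developmental, slow, cardiac or ubiquitous gene as first member and an adult, fast or muscle gene as second in most pairs. The regulator pairs Myf5 and Myod1, Myf6 and Myog, Id1 and Id3, and Pax7 and Pax3, and the pair of Myh3 with the perinatal Myh8, do not follow that order. Of 30 pairs, 15 had more reads of the second member, 14 had more of the first, and 1, the phosphoglycerate mutase pair Pgam1 and Pgam2, was not called (873 against 865 and 985 against 925 reads, largest adjusted exact binomial p = 0.867). In the thin filament and sarcomere, Acta1 exceeded the cardiac actin gene Actc1 8.27-fold ± 0.0375, Tnnt3 exceeded the slow Tnnt1 2.35-fold ± 0.158, Myl1 exceeded the embryonic Myl4 2.21-fold ± 0.104, Mylpf exceeded Myl2 106-fold ± 11.3, and the muscle actinin gene Actn2 exceeded Actn1 10.03-fold ± 0.236. Of the metabolic pairs, muscle creatine kinase Ckm exceeded Ckb 3.64-fold ± 0.181, Ldha exceeded Ldhb 56.2-fold ± 10.8, Pfkm exceeded Pfkl 4.05-fold ± 0.816, Cox6a2 exceeded Cox6a1 1.55-fold ± 0.00780 and Eno3 exceeded Eno1 1.34-fold ± 0.00243. Calcium handling gave Atp2a1 over Atp2a2 at 5.04-fold ± 0.0116 and Ryr1 over Ryr3 at 25.4-fold ± 9.11. Among regulators, Myod1 exceeded Myf5 42.8-fold ± 2.82, Id3 exceeded Id1 3.75-fold ± 1.30, and Myog had 6569 and 7270 reads against 8 and 2 for Myf6.

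In the other direction, Myh3 exceeded Myh1 3.60-fold ± 0.177, Myh4 10.8-fold ± 3.08, Myh7 19.4-fold ± 0.0983 and Myh8 21.7-fold ± 3.24, and had 5073 and 6221 reads against 3 and 3 for Myh2. The cardiac troponin T gene Tnnt2 exceeded Tnnt3 1.45-fold ± 0.118, the slow troponin genes Tnni1 and Tnnc1 exceeded Tnni2 4.45-fold ± 2.36 (2.78 and 6.12 in replicates 1 and 2) and Tnnc2 1.64-fold ± 0.00384, and Casq2 exceeded Casq1 2.11-fold ± 0.115. The fetal acetylcholine receptor subunit gene Chrng exceeded the adult subunit gene Chrne 62.0-fold ± 15.6. The ubiquitous genes Cox7a2, Cox8a and Slc2a1 exceeded Cox7a1, Cox8b and the insulin-responsive glucose transporter gene Slc2a4 8.25-fold ± 0.708, 2.83-fold ± 0.147 and 5.71-fold ± 0.352. Pax7 had 31 and 29 reads and Pax3 had 0. Among the 29 called pairs the largest adjusted exact binomial p was 0.0017, for Id1 and Id3. Over the exons of Tnni2, reads were also assigned to the gene Syt8 in replicate 2 (486 reads).

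By class, known transcripts held 55.2% ± 1.73 of endogenous reads and incomplete splice matches 19.6% ± 0.443, of which models lacking 5′ exons made up most (13.6% ± 0.139 of all reads). Unannotated-chain transcripts held 8.57% ± 0.172, with 8.45% (exact 95% interval 8.42 to 8.49) in replicate 1 and 8.70% (8.66 to 8.73) in replicate 2. Genomic, antisense and intergenic models held 9.78% ± 0.989, 6.01% ± 0.408 and 0.908% ± 0.0668. The genomic and incomplete match classes were not assigned alike in the libraries. All single-exon reads of Rplp0 in these 2 classes were genomic in replicate 1 (2464) and incomplete matches in replicate 2 (1856), and in 565 of 2442 genes with at least 20 such reads in each library most of them had the other class in the other library (2.45% and 2.04% of endogenous reads). Genes with longer known transcripts had a larger share of incomplete matches (Spearman's rho = 0.325 across 8361 genes, permutation p = 1e-05, the smallest the permutations can give; rho 0.303 and 0.324 in the libraries). The median share was 7.99% in genes whose longest known transcript had at most 1947 nt and 24.6% in those with at least 4342 nt.

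Of 8615 genes with at least 20 reads in each library and a known or unannotated-chain model, 1418 (16.5%) had more than 1 major isoform and 127 had 3 or more. The most-read model was the same in both libraries in 7667 genes (89.0%). In the list of 70 genes with muscle splice forms, 68 had at least 20 reads in each library and 27 had the same first transcript, called against the second in both libraries. In the pyruvate kinase gene Pkm, Pkm-202, with the coding exon at 59675029 to 59675195 on chromosome 9, held 48.0% ± 1.66 of the gene's reads, and Pkm-201, with the alternative coding exon at 59675568 to 59675734, held 29.5% ± 0.642. The upstream exon of this pair is that of the muscle form M1. The tropomyosin genes Tpm1 and Tpm2 were dominated by Tpm1-205 (69.5% ± 5.37) and Tpm2-202 (69.5% ± 1.79), and the light chain gene Myl1 by Myl1-202 (54.3% ± 1.01), which has a 25-nt coding exon where Myl1-201 (10.9% ± 1.36) has one of 28 nt, and another first exon (79 nt against 352 nt). First transcripts of Atp2a2 (Atp2a2-202, 51.7% ± 1.89), the translation factor gene Eif4g2 (Eif4g2-213, 62.9% ± 0.648), the splicing factor gene Rbm24 (Rbm24-201, 26.9% ± 2.70) and Itgb1 (Itgb1-201, 55.9% ± 2.72) were annotated. In the splicing factor genes Mbnl1 and Mbnl2 and in Pdlim5 the first transcript was unannotated (13.9% ± 0.236, 35.6% ± 6.03 and 39.9% ± 1.04 of the reads). The Mbnl1 model contained a 95-nt coding exon at 60622146 to 60622240 on chromosome 3 that the second model lacked, and the Mbnl2 model lacked a 95-nt coding exon at 120404638 to 120404732 on chromosome 14. Bin1 was not called, because its leading intron chain (1094 and 1298 reads) was deposited in different classes in the libraries.

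Atp2a1 also had the most-read unannotated-chain transcript of all genes. This 21-exon model (126445858 to 126463108 on chromosome 7, minus strand) had 9366 and 10145 reads, 61.1% ± 1.09 of the gene's reads. It used an intron at 126462188 to 126462778 that is absent from M21, where the annotated Atp2a1-201 has an 18-nt exon at 126462500 to 126462517 and a first exon that is 304 nt long and not 330 nt. The short annotated Atp2a1-202 held 16.1% ± 0.858. All introns of Atp2a1-202 are also in the 21-exon model, and its first exon lies inside an exon of that model. Reads of the longer transcript that lack 5′ exons therefore cannot be told apart from Atp2a1-202. A 22-exon model with the intron absent from M21 had 870 and 946 reads and contained a 42-nt exon at 126446545 to 126446586. In all, 2788 unannotated-chain transcripts in 1748 genes had at least 5 reads in each library. Of these, 1293 combined introns that are all in M21, 345 had an intron absent from M21 between annotated sites only, and 1150 had an unannotated splice site. Of the 125048 seen in either library, 19920 (15.9%) were seen in both. In the other most-read models, apart from that of Tnni1, every intron was in M21 and the combination was not. They were those of Oaz1 (3083 and 3436 reads), Eno1 (1871 and 2190), the troponin gene Tnni1 (1731 and 1977), Srl (1412 and 1566), Aldoa (696 and 854) and Ctbp1 (717 and 729). The Oaz1 model equals a known transcript once annotated gaps of at most 10 nt are closed, which holds for 7 models and 2.09% and 2.18% of the unannotated-chain reads. The Tnni1 model joined annotated sites across 135802624 to 135805052 on chromosome 1.

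**Figure D3:**
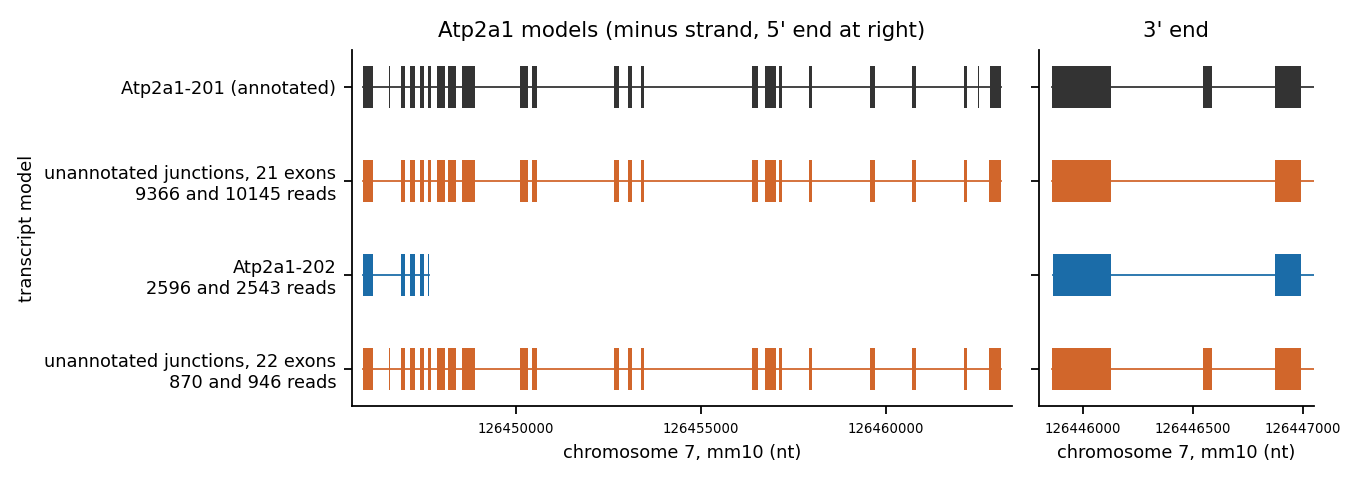
Exons (boxes, to scale) of the annotated Atp2a1-201 and of the 3 most-read Atp2a1 models on chromosome 7, with the reads in replicates 1 and 2 and the 3′ end enlarged at right. The model with 9366 and 10145 reads lacks the 42-nt exon that the model with 870 and 946 reads contains.

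The replicate libraries were compared gene by gene. Mymx, which encodes a microprotein required for myoblast fusion (ENSMUSG00000079471.4, chromosome 17, 45600971 to 45602102), had 1146 reads in replicate 1 and 307 in replicate 2, a 3.89-fold difference (Fisher's exact test, adjusted p = 3.36e-118). The fast troponin I gene Tnni2 (chromosome 7, 142441808 to 142444410) had 1083 and 546 reads, a 2.07-fold difference (adjusted p = 5.83e-43). These were the only members of the fixed lists that were called, over all genes tested and also adjusted over the list alone. These p-values cover counting error only. Over the exons of Mymx, the neighbouring gene Slc29a1 had 4 reads in replicate 1 and 644 in replicate 2, and over those of Tnni2 the neighbouring gene Syt8 had 0 and 486. Of 11863 genes tested, 307 had an adjusted p under 0.05 and 96 (0.809%) were also at least 2-fold apart, 32 higher and 64 lower in replicate 2 (Fisher's exact test, Benjamini-Hochberg over all genes). Of the 96, 61 were protein-coding and 20 pseudogenes, against 324 pseudogenes among the genes tested.

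With a count of 0 taken as 3 reads and other counts as they are, the called genes with the largest fold toward replicate 2 were the pseudogene Rpl21-ps9 (0 and 334 reads, at least 107-fold against 3 reads in replicate 1), Syt8 (13 and 502, 37.0-fold), Gm26724 (0 and 85, at least 27.2-fold), Gm12033 (1 and 27) and Gm44965 (3 and 64). Those with the largest fold toward replicate 1 were Gm49369 (133 and 1 reads), 1700008O03Rik (352 and 5, 73.4-fold), Gm49486 (57 and 1), Ggnbp1 (38 and 1) and Gm28036 (53 and 3). This limit places lower the other called genes with 0 reads in a library and at least 20 in the other, which were Gm14018 (0 and 40), AC109138.7 (0 and 33), 9830144P21Rik (0 and 27), Vil1 (49 and 0), Gm28039 (33 and 0), Gm47093 (25 and 0) and 4930520M14Rik (20 and 0). For the genes with the largest folds except Gm12033, reads of other gene models over the same exons moved the other way. With these reads added, replicate 2 over replicate 1 was 0.913 for Rpl21-ps9, 0.859 for Syt8, 1.03 for Gm26724 and 0.851 for Gm44965. It was 1.15 for Gm49369, 1.02 for 1700008O03Rik, 0.887 for Gm49486, 0.959 for Ggnbp1 and 0.949 for Gm28036. These folds therefore need not be differences in RNA. Across the tested genes the libraries had a Pearson r of 0.972 on log2(CPM + 1) and a Spearman rho of 0.978, where genes are not independent replicates. The median absolute log2 ratio was 0.15 in genes with at least 50 reads, and the median chi-square per gene was 0.702 against 0.455 from counting error alone, so the libraries differed by more than sampling noise. With an assumed biological dispersion of 0.1 (edgeR exact test), 18 genes were called, and with known transcripts only, 28 (Fisher's exact test).

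Transcript usage differed for 304 of 228615 transcripts, in 204 genes (Fisher's exact test, Benjamini-Hochberg). Of these, 192 were single-exon or incomplete splice match models, 105 known and 7 unannotated-chain transcripts. With reads of known transcripts only, 24 differed. In Mymx, single-exon reads classed as genomic numbered 852 in replicate 1 and 0 in replicate 2, whereas the known Mymx-203 had 192 and 230 reads. Among lists, the median log2 ratio of glycolysis genes (0.11) stood at the 99.3 percentile of 10000 matched lists and that of the fibroblast and matrix list (0.13) at the 98.9 percentile, while oxidative phosphorylation (−0.06) stood at 0.810 and the non-coding list (−0.35) at 0.0400. These percentiles describe these libraries only and were not adjusted over the lists. That of the non-coding list rests on 8 of its 13 members.

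**Figure D4:**
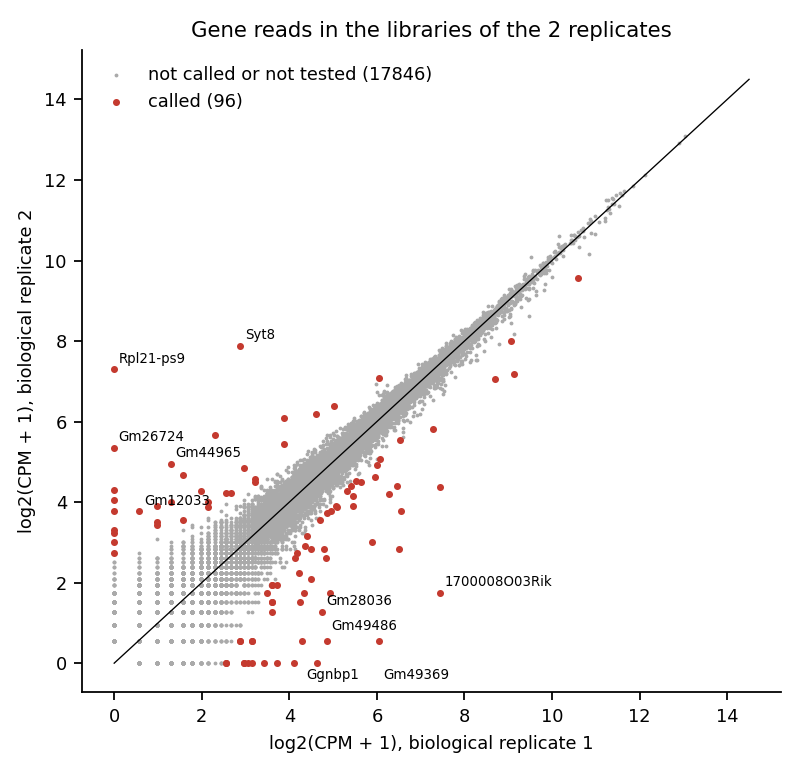
Each point is an annotated gene, at log2(CPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with the line of equal values. The 96 called genes are red and the 10 named by fold are labelled, with Rpl21-ps9 at 0 and 334 reads farthest above the line at 0 CPM in replicate 1.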

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

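The search for sites of the 5′ part of 28S ribosomal RNA was chosen only after the first 28S test below had come out at 0. An antisense single-exon model on the minus strand of chromosome 17, at 39843013 to 39846245 (mm10) opposite the non-coding RNA Gm26917, stood out because it lies outside the annotated genes and exceeds the limit that a count of 0 allows. It had 22689 reads in replicate 1 and 20398 in replicate 2, or 1.11% and 0.957% of endogenous reads, more than Acta1. Over the region from Gm26917 to Gm42418, the minus strand held 23195 and 20866 reads and the plus strand 1501 and 1329. The annotated transcript of Gm42418, on the plus strand, contained 2 of 2 conserved 18S ribosomal RNA sites in sense orientation.

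A candidate explanation was 28S ribosomal RNA read from the minus strand. The sarcin-ricin loop of 28S, a strictly conserved motif, was found 0 times in the reverse complement of the annotated transcript of Gm26917. It was found in Lars2 when all 141767 annotated transcripts were searched. This argues against the part of 28S that holds the loop, but only for the stretch of the model that the Gm26917 transcript covers. Of 3 sites of the 5′ part of 28S, 0 were found there, but 0 of these sites occurred in any annotated transcript, so that search had no positive control and a 5′ fragment of 28S cannot be told apart from other sources of the reads. The 18S sites were searched in Gm42418 only, where 0 of 2 lay on the minus strand. Other parts of the ribosomal RNA precursor were not tested. The design gives a single group, so no biological explanation was tested.

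The spike-in RNAs were used in no comparison, and both families were read above the limit that a count of 0 allows. ERCC spike-ins had 1605 reads in replicate 1 and 1980 in replicate 2, all in known models, with 0 unannotated-chain reads, which allows a share of up to 0.187% and 0.152%. SIRV spike-ins had 279 and 304 reads, and 33.3% and 59.2% of these were in unannotated-chain models, where the deposited annotation holds 1 model per SIRV gene.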

How the results depend on the processing

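The alternatives that count an intron chain of the unannotated-chain class in either library as such in both, and that leave pseudogenes out, were chosen only after the data were seen. Of 52 alternatives to the main settings, 6 could not move the value, since leaving out 1 of 2 replicates moves a mean share by less than 1 SD. Of the other 46, 30 kept the result and 16 moved it. A reversal could be found only for the sarcomere difference, where none occurred. Kept means the same side of the threshold for the sarcomere difference, within 1 SD for shares and within 1.5 times the main value for counts. The sarcomere difference of 3.60 stayed past its threshold but fell to 1.86 with known transcripts only and 2.55 without genomic and incomplete splice match models, and otherwise lay between 3.39 and 3.89. Of 30 paralog pairs, 12 had more reads of the second member and 12 more of the first with known transcripts only. Every other setting gave 15 and 14. Over known transcripts only, the early share of myosin heavy chain reads was 86.2%, 28 genes differed between the libraries (19 of them among the main 96) and 24 transcripts differed in usage. Without genomic and incomplete splice match models the early share was 84.6%. The number of genes differing was 52 with at least 50 reads, 18 with an assumed dispersion of 0.1 and 307 without a fold minimum, by construction of those settings, 100 with either TMM or DESeq2 scaling, and 74 without pseudogenes. The unannotated-chain share was 5.02% over transcripts with at least 5 reads in each library, 9.60% without genomic and intergenic reads in the denominator and 8.81% when an intron chain of that class in either library was counted in both. The share of incomplete splice matches was 17.7% over transcripts with at least 5 reads in each library and 20.5% over multi-exon models. A 20% minimum for a major isoform left 425 genes. Unannotated-chain transcripts numbered 1298 at 10 reads and 7963 at 2 reads in each library, and 3972 to 4292 in a single library, where fewer conditions apply (4292 without replicate 1). For known transcripts only, the cause was not tested. No paired analysis was possible because the series has a single group. Depth limited the rarest genes, since 3 reads correspond to 1.47 and 1.41 CPM, and genes with longer transcripts had a larger share of incomplete reads.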

Other observations

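The tests of assignment to another gene model, of gene length, of the counting error of family offsets and of parents without the reads of their pseudogenes, and the values for genes on no list and for the Atp2a1 exon, were chosen only after the results were seen. Among protein-coding genes on no fixed list, the most read were the galectin gene Lgals1 (2799 ± 240.1 CPM), the heparan sulfate proteoglycan gene Gpc1 (2675 ± 46.6 CPM), the desaturase gene Scd2 (2639.6 ± 336 CPM) and the IGF-binding protein gene Igfbp5 (2444 ± 23.6 CPM). The tubulin genes Tuba1b (1892 ± 71.9 CPM) and Tubb2a (1463 ± 2.53 CPM), the nuclear lamin gene Lmna (1404 ± 37.0 CPM) and the muscle adenine nucleotide translocator gene Slc25a4 (1378 ± 14.9 CPM) were also among the first 20. Cytosolic ribosomal protein genes together held 3.57% and 3.07% of reads, over 82 genes, without the reads assigned to their pseudogenes. Collagen genes held 0.460% and 0.504%, over 35 genes, and Col3a1 alone had 5451 of their 9397 reads in replicate 1 and 6361 of 10741 in replicate 2.

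In Atp2a1, the 42-nt penultimate exon that is kept in the adult form of the calcium pump and skipped in the neonatal form was included in 1224 reads and skipped in 13763 in replicate 1, a share of 8.17% (exact 95% interval 7.73 to 8.62). In replicate 2 it was included in 1324 and skipped in 14415, a share of 8.41% (7.98 to 8.86), which gives a mean of 8.29% ± 0.173. The antisense model with the second most reads, at 101221717 to 101221997 on the minus strand of chromosome 12, had 3426 and 2165 reads. It lay opposite the pseudogene Gm18795 and over the pseudogene Mylf-ps, which is on the same strand as the model. The intergenic loci with the most reads were at 31545792 to 31549650 on the plus strand of chromosome 11 (550 and 642 reads) and at 99877616 to 99877816 on the minus strand of chromosome 6, over the pseudogene Tpt1-ps3 (396 and 317 reads). The same unannotated intron chain was deposited in different classes in the libraries for 515 of 11500 chains with at least 5 reads in each library (4.48%).

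The 96 genes that differed between the libraries may in part be reads of the same molecules that were given to different gene models. Other genes' reads over the called gene's exons offset a median of 35.5% of its change over all 96, with quartiles of 0 and 87.1%, so that reassignment cannot be told apart from a difference in RNA for the set as a whole. For the 59 genes with any such reads the median was 82.7%, as in Rpl21-ps9, where an unannotated model had 351 and 0 reads, and 12 of them form 6 pairs that hold each other's reads. With each pair counted once, the other reads moved against the called gene in 50 of 53 loci and with it in 3 (exact sign test across loci, p = 5.52e-12). Another gene's reads were counted where their model overlapped the called gene's most-read model by at least 50% of the shorter one's exons. The other 37 genes had none, but 21 of them had reads of another gene on some exon. The genes were parted by the reads that were sought, so reassignment stays open for these 21. The rest had no same-strand read of another gene on any exon, which argues against reassignment to an overlapping model for them. Among them were Ezh2 (87 and 36 reads), H2-K1 (99 and 46) and Mapk8 (61 and 27). Transcript length, fitted over uncalled genes with at least 50 reads, predicted 1.47% of the median change (0.03 against 2.21 on the log2 scale). In those uncalled genes the log2 ratio hardly followed length (Spearman's rho = 0.07). The fit left out every gene called as at least 2-fold apart, so a prediction near their change was hardly possible. It cannot decide on length for the called genes. Of 19 called pseudogenes with a family of similar sequences, the family's reads moved the same way in 15. The median offset over the 19 was −111% (order-statistic interval of the median −247 to −12.4). That interval covers the spread across pseudogenes. In several the family had far more reads than the pseudogene, as in Rps12-ps16 (25 and 6 reads, family 576 and 357). A shift of the family itself could therefore hide an exchange, so the offset does not decide and exchange within families stays open for the set. The 95% interval of the offset (normal approximation) covers the counting error of the family's reads only. Counting error of the pseudogene's own reads and such a shift are not covered. The interval reached 50% in 4. These were Rpl3-ps2 (offset 1212%), Gm13456 (2407%), Gm11196 (19.8%, interval −56.7 to 96.3) and Gm12346 (−189%, interval −484 to 106). In Gm13841, whose family also moved the other way, the offset was 1.12% (interval −35.3 to 37.5). Some of these pseudogenes were instead offset over their own exons. Ssh2 had 0 and 19 reads over Gm12346, and unannotated models had 53 and 0 over Gm12715 and 42 and 0 over Gm14018. The source of the difference for the 37 genes stays open, and no biological explanation was tested.

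Pseudogenes with many reads in both libraries may carry reads of their parent mRNAs. Of 61 pseudogenes with at least 100 reads in each library, 91.8% aligned to a protein-coding transcript at 95% identity or more over 80% of their length, against 15.6% of 1000 processed pseudogenes with no read (one-sided Fisher's exact test p = 2.62e-36). The median CPM of parent and pseudogene together lay at the 96.5 percentile of the genes tested, but the pseudogenes were chosen by their reads and lay at 85.2 alone, so this value decides nothing. The 47 parents alone had a median at the 92.1 percentile (203 CPM), against 74.9 (73.0 CPM) for the 123 parents of pseudogenes with no read, 23 of which are in both sets (two-sided permutation test across genes, p = 0.00202). In 24 of the 61, among them Gm15459 (parent Hspa8), Rpl3-ps1 (3682 and 4166 reads against 178 and 196 for Rpl3) and Gm13394 (parent Gapdh), the pseudogene exceeded the parent in both libraries. Transcription of the pseudogenes themselves stays open and was not tested.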
